A study of Mus musculus with 4 samples.

How the data were processed

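Total RNA of liver mitochondria was measured in 4 libraries, 1 each from wild-type, ob, NASH and db mice of postnatal week 7. Per the labels' protocols, RNA was extracted with the miRNeasy Mini Kit, and libraries were made with the NEBNext Ultra Directional kit, which keeps the strand, after ribosomal RNA depletion. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic 0.32, TopHat2 2.1.1 and Bowtie2 2.3.2 were used with genome build mm10. The program that counted reads per gene, its annotation, its strand setting and its treatment of reads with several places are not given in the sources used here. How the mitochondria were purified and what brought about the NASH state are not given there either.

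The deposited table held 37819 features on 21 chromosomes (19 autosomes, X and Y), and 0 features on the mitochondrial chromosome. Per the file headers and their values, it gave raw expected counts per feature and library, with fractions, from the authors' counting. Within 0.01 of a whole number were 89.5% of counted features in wild-type, 53.7% in ob, 89.3% in NASH and 85.3% in db. Per the file headers, the authors also deposited TMM-normalized values on a log2 scale. By their values, these were the log2 of the raw count plus 1 constant per library (0.56 in wild-type, -0.87 in ob, 0.61 in NASH and -0.23 in db), with values under 0 set to 0. They served only to check the table and as an alternative scaling. Of the feature IDs 36049 (95.3%, and 99.6% past the filter) were in the GENCODE M21 annotation, from which current names came. Biotypes and positions came from the deposited table.

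Expected counts were rounded to whole counts. Features with at least 10 counts in at least 1 of the 4 libraries were tested, which left 5347. Counts were scaled with TMM factors from edgeR 4.0.16 (calcNormFactors, R 4.3.3), which were 0.687 in wild-type, 1.51 in ob, 0.921 in NASH and 1.05 in db. Fold changes were differences of log2(CPM + 1), where CPM is counts per 1000000 of the scaled library, and a feature was called higher or lower at 2-fold or more, with no test, since 1 library per group allows none. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest. Folds of named genes are ratios of scaled counts without a pseudocount, with exact binomial 95% intervals, and shares have exact Clopper-Pearson 95% intervals. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Where 1 library had 0 counts, the fold was computed against a floor of 3 counts in that library and is a lower bound, and no fold is given where both were at or under the floor. The floor was 6.95 CPM in wild-type, 1.99 in ob, 6.15 in NASH and 2.84 in db. Outside the features resembling mtDNA genes, 293612 counts were left in wild-type, 713285 in ob, 129834 in NASH and 741471 in db.

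The filter, scaling, thresholds, gene lists and the rule for named genes were fixed before the data were examined. For each comparison with wild-type, the rule named the 10 largest increases and the 10 largest decreases among features with at least 50 counts in the higher library, the 5 largest per direction among non-coding features, and up to 4 members of each list with the largest changes. Lep, Lepr, Nnt and the sex-linked genes were named whatever their values, as were the 10 features per direction with the largest smallest change among those changed in all 3 models. For db against ob it named the 5 largest changes per direction, and the other genes named in that comparison, members of the lists, were chosen after the data were seen. Genes whose reads near-identical copies can share (Mup, hemoglobin, Serpina1, Saa1 and Saa2, Cyp2, Cyp3a and Cyp4a, Ugt1a, H2, U3, U1 and U2, signal recognition particle RNA and pseudogenes) are uncertain. The comparison by class used the biotypes of the deposited table.

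The gene lists covered mtDNA-encoded messenger, transfer and ribosomal RNAs, nuclear-encoded RNAs reported in mitochondria, nuclear-retained and liver-related long non-coding RNAs, and cytoplasmic structural RNAs. They covered respiratory complex subunits, mitochondrial and cytosolic ribosomal proteins, mtDNA maintenance, secreted hepatocyte proteins, fat synthesis, lipid droplets, cholesterol, fatty acid oxidation, ketogenesis, glucose handling, bile acids, amino acids and urea, xenobiotic metabolism, sex- and growth-hormone-dependent genes, acute phase, integrated stress and oxidative stress. Cell type and control lists covered fibrosis, macrophages, endothelium, cholangiocytes, erythroid cells, adipocytes and pancreas, sex-linked genes, the leptin pathway, Nnt, cell cycle and clock genes. A list with at least 3 members past the filter has a median log2 fold change and its percentile among 10000 random lists matched on expression decile. Overlaps of calls were set beside the overlap of independent lists and beside 100 simulated sets of unchanged groups that share a wild-type library. In these sets every library, wild-type included, was drawn from the same mean profile with counting noise only. They hold no spread between animals or preparations, so calls above their level do not show a difference between conditions.

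The planned share of mtDNA-encoded RNA could not be computed, since the table holds none of the 37 mtDNA genes of the annotation. In its place, transcripts of features past the filter were compared with the mtDNA genes by BLAST 2.17.0, and 9 features with at least 85% identity over at least 100 bases were taken as resembling mtDNA genes, a choice made after the data were seen. In the same way, 4 features annotated as microRNAs were found to be copies of 1 repeat of 57 bases.

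The scripts were tested on simulated data in which 200 genes per model changed by known folds, over 3887 features. Of these, 153 passed the filter for ob against wild-type, 144 for NASH and 154 for db. Of those past the filter, 91.8% of 4-fold and 45.7% of 2-fold changes were called for ob, 93.3% and 45.3% for NASH, and 98.1% and 50% for db. Of all changed genes these shares were 70% and 33.9% for ob, 67.7% and 29.6% for NASH, and 76.8% and 37.1% for db. Of unchanged features past the filter 11.2% were called for ob, 16.0% for NASH and 11.2% for db. Counting intervals covered equality for 91.3% of unchanged features with at least 50 counts for ob, 95.0% for NASH and 93.8% for db. Apart from the changed genes, the simulated libraries shared the same mean profile with counting noise only. Their TMM factors were 1.009 for ob, 0.990 for NASH and 1.002 for db. These shares therefore do not cover the differences in composition and scaling between the real libraries.

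Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter of 50 counts, median-of-ratios size factors (the estimator of DESeq2 1.42.0), upper-quartile scaling, plain library totals, and fold thresholds of 1.5 and 4. Added after the data were seen were the submitters' scaling, the features resembling mtDNA genes left out of the library total, calls that also need a counting interval excluding equality, counts of 0 set at the floor, and the ob or the NASH library left out of filter and scaling. Summed counts of RNA classes over all features, without the filter, and of lists without single members were added then too. No library was left out of the main comparisons. Some single genes are not reported here.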

Results

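The series set out to compare the RNA species of liver mitochondria, non-coding RNAs in particular, between mouse models of metabolic disease. Total RNA of liver mitochondria was sequenced after ribosomal RNA depletion in 4 libraries, 1 per group, from mice of postnatal week 7. The groups were wild-type C57BL/6J, ob (B6.Cg-Lepob/J, which carry a leptin mutation), NASH and db. NASH were wild-type mice with non-alcoholic steatohepatitis, whose diet or treatment is not given in the sources used here. The genotype label of db names BKS mice with Leprdb, a leptin receptor mutation, while its strain label names C57BL/6J. The library totals were 627890 counts in wild-type, 1000306 in ob, 529815 in NASH and 1005915 in db. At least 10 counts were reached by 1368 features in wild-type, 4744 in ob, 1238 in NASH and 2895 in db. With 1 library per group, no difference has a replicate check. Ranges in parentheses are exact 95% counting intervals, which cover counting error only and compare libraries, not conditions.

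The genes mutated in the models were at or near the detection floor. Lep, the leptin gene, had 0 counts in every library, which allows a level of up to 6.95 CPM (counts per 1000000 of the scaled library) in wild-type, 1.99 in ob, 6.15 in NASH and 2.84 in db (3 counts in each library). Lepr, the leptin receptor gene, had 0 counts in wild-type, 4 in ob, 0 in NASH and 2 in db. Its neighbour Leprot had 1, 5, 3 and 3 counts in the same order. These counts can neither bear out nor contradict the genotype labels.

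A few features held most of each library. Genes of the mitochondrial chromosome had no features in the table, and 9 nuclear features that resemble mtDNA genes in sequence took 53.2% of wild-type counts (53.1 to 53.4), 28.7% of ob counts (28.6 to 28.8), 75.5% of NASH counts (75.4 to 75.6) and 26.3% of db counts (26.2 to 26.4). The most abundant of them was Gm13340 (ENSMUSG00000083563, mm10 chromosome 2, 22588103 to 22589647, minus strand), a pseudogene 97.6% identical to mt-Co1 over 1545 bases, with 25.8%, 14.7%, 38.6% and 13.2% of counts in wild-type, ob, NASH and db. Next came Gm20594 (ENSMUSG00000096887, chromosome 6, 79818031 to 79818364, plus strand), which resembles the mitochondrial 16S ribosomal RNA gene mt-Rnr2, with 15.1%, 7.82%, 23.4% and 7.59%. Signal recognition particle RNA, the RNA core of the particle that brings ribosomes to the endoplasmic reticulum, took 11.9% of wild-type, 23.1% of ob, 10.8% of NASH and 9.43% of db counts. Copies of a 57-base repeat annotated as microRNAs took 10.2%, 5.67%, 2.03% and 6.53%. Protein-coding features other than those resembling mtDNA genes took 24.2% in wild-type, 40.1% in ob, 11.5% in NASH and 57.1% in db, and albumin mRNA (Alb) alone took 2.62%, 4.24%, 0.420% and 10.1%. Shares and scaled levels can differ. Under TMM scaling, the 9 features resembling mtDNA genes had a median log2 fold change of -2.08 in ob, with 9 at least 2-fold lower. It was -0.39 in NASH, with 0 higher and 0 lower, and -1.81 in db, with 9 lower. Signal recognition particle RNA stood at 172867 CPM in wild-type and 153766 CPM in ob.

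**Figure D1:**
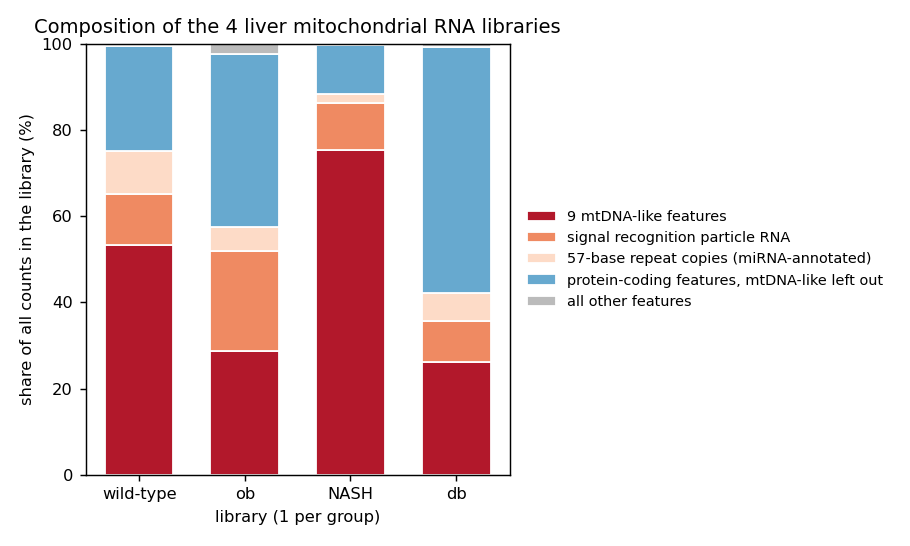
Share of all counts in percent (vertical axis) by kind of feature in each of the 4 libraries (stacked bars, 1 library per group). Features resembling mtDNA genes ranged from 26.3% in db to 75.5% in NASH, and protein-coding features other than these from 11.5% in NASH to 57.1% in db.

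The choice of scaling moved all genes together. Under trimmed-mean (TMM) scaling the median log2 fold change over the 5347 features tested was 0.41 in ob, -0.14 in NASH and 0.11 in db against wild-type, and -0.17 in db against ob. Over 6 scalings it ranged from 0.41 to 1.41 in ob, from -0.14 to 0.85 in NASH, from 0.07 to 0.62 in db and from -0.67 to -0.04 in db against ob. Gene list medians are given below without subtracting these medians. Beside each stands its percentile among 10000 random lists of equal size matched on expression, as a description of these libraries. Where setting counts of 0 at the floor of 3 counts moved a median by 0.1 or more, that value is given too.

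The comparison of ob with wild-type asked how the RNA of liver mitochondria differs without leptin. The nuclear-retained long non-coding RNAs Neat1 and Malat1 were far higher in the ob library. Neat1, the scaffold RNA of nuclear paraspeckles, was 305-fold higher (148 to 759, with 7450 counts against 7), and Malat1, an RNA of nuclear speckles, was 26.0-fold higher (20.7 to 33.1). Genes of fat synthesis and storage were higher too, among them Scd1, the stearoyl-CoA desaturase, at 9.0-fold (8.16 to 9.95), and Apoa4, an apolipoprotein gene induced in fatty liver, at 68.3-fold (34.6 to 158). Most sex- and growth-hormone-dependent genes on the list used here were lower, with Mup7, a major urinary protein gene, 22.3-fold lower (20.1 to 24.7).

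Of the 6 measured nuclear-retained RNAs 4 were at least 2-fold higher and 1 lower in ob, with a median log2 fold change of 3.87 (1.54 with counts of 0 set at the floor, percentile 100), and their summed level was 26.0-fold higher (22.2 to 30.5). Neat1 and Malat1 held 97.0% of the list's ob counts, and without them it was 1.56-fold higher (1.23 to 2.01). Neat1 (ENSMUSG00000092274) lies on mm10 chromosome 19 from 5824708 to 5845478 on the minus strand, and Malat1 on chromosome 19 from 5795690 to 5802672. Summed over all features without the filter, small nuclear RNAs had 757 counts in ob and 33 in wild-type and were 6.57-fold higher (4.64 to 9.62). Small nucleolar RNAs had 1643 and 41 and were 11.5-fold higher (8.43 to 16.1), and long non-coding RNAs had 16136 and 430 and were 10.8-fold higher (9.77 to 11.9), most of it Neat1 and Malat1. Counts of single features depend on the filter, since all 26 small nuclear, 22 of 26 small nucleolar and 26 of 35 long non-coding features passed it through ob alone. Of these classes 26, 25 and 25 features were higher (medians 2.31, 3.42 and 2.93) and 0, 0 and 1 lower, but 23, 17 and 12 were higher with counts of 0 at the floor (medians 2.1, 1.84 and 0.52). The 26 small nuclear features are 12 copies of U1, 11 of U2, 2 of U4 and 1 of U5. Of the small nucleolar features, 5 are copies of U3. Copies can share reads, so these features are not independent. The share of small nuclear RNA was 0.0757% of ob counts (0.0704 to 0.0813) and 0.00526% of wild-type counts (0.00362 to 0.00738). SCARNA6, which guides modification of small nuclear RNAs in Cajal bodies, was at least 10.3-fold higher, and the nucleolar U3 RNA, which acts in ribosomal RNA processing, was 11.6-fold higher (4.88 to 36.0) at its most abundant copy, where copies of the gene can share reads. RNase_MRP (Rmrp), an RNA with roles in ribosomal RNA processing and reported in mitochondria, was 12.8-fold higher (9.25 to 18.2), whereas RNaseP_nuc (Rpph1), the RNA of the tRNA-processing ribonuclease P, was 2.23-fold lower (1.68 to 2.95). 7SK, which restrains transcription elongation, was 1.80-fold higher (1.36 to 2.43). All 5 features annotated as microRNAs were lower (median -1.92), of which 4 are copies of the 57-base repeat, with AC087541.1 3.89-fold lower (3.84 to 3.94).

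Genes of fatty acid and triglyceride synthesis were higher in 9 of 16 members and lower in 0, with a median of 1.62 (percentile 100) and a summed level 6.94-fold higher (6.41 to 7.54). Scd1 held 86.3% of the list's ob counts, and without it the level was 2.84-fold higher (2.46 to 3.30). Mlxipl, which encodes the carbohydrate-sensing transcription factor ChREBP (chromosome 5, 135106891 to 135138382), was 100-fold higher (17.8 to 3961, from 1 count in wild-type). Srebf1, the gene of the lipogenic factor SREBP-1, was 19.8-fold higher (7.64 to 73.1), and Acacb, an acetyl-CoA carboxylase gene, 10.9-fold (2.91 to 91.5). Scd1 lies on chromosome 19 from 44394451 to 44407709. Of 11 lipid droplet and PPARgamma-linked genes 7 were higher and 1 lower, with a median of 2.11 (1.05 with counts of 0 at the floor, percentile 98.9). Cd36, a fatty acid uptake receptor gene, was 8.05-fold higher (4.55 to 15.7), Plin4, a lipid droplet coat gene, at least 6.40-fold, and G0s2, an inhibitor of triglyceride breakdown, at least 4.78-fold. Apoa4 lies on chromosome 9 from 46240696 to 46243459.

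Fatty acid oxidation genes were higher in 13 of 25 members and lower in 1 (median 1.07, percentile 99.8), with Cyp4a14, a fatty acid hydroxylase gene with close copies, 8.30-fold higher (6.24 to 11.3), Vnn1, a pantetheinase gene, 14.5-fold (3.90 to 121) and the peroxisomal thiolase gene Acaa1a 6.40-fold (2.86 to 17.8). Glucose-handling genes were higher in 8 of 13 and lower in 0 (median 1.34, 1.07 with counts of 0 at the floor, percentile 88.9), with Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase gene, 6.80-fold higher (3.23 to 17.2). Amino acid and urea genes were higher in 8 of 11 and lower in 0 (median 1.15, percentile 99.8), with the urea-cycle gene Cps1 3.47-fold higher (2.65 to 4.62). Of 12 bile acid genes 4 were higher and 2 lower (median 0.57, percentile 98.3), with the bile acid synthesis gene Hsd3b7 8.81-fold higher (3.36 to 32.9). Of 16 cholesterol genes 3 were higher and 1 lower (median 0.30, 0.12 with counts of 0 at the floor, percentile 80.6). Of 23 xenobiotic genes 6 were higher and 2 lower (median 0.45, 0.26 with counts of 0 at the floor, percentile 97.1), led by Cyp2a4 at 38.5-fold (10.6 to 319.9) and Cyp2a5 at 9.57-fold (6.62 to 14.4), which are near-identical copies whose reads cannot be told apart with certainty. Erythroid genes were higher in 5 of 5 (median 3.35, percentile 99.99), with the hemoglobin gene Hba-a1 14.3-fold higher (8.64 to 25.8), again among close copies.

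Sex- and growth-hormone-dependent genes were lower in 13 of 20 members and higher in 3, with a median of -2.96 (percentile 0.0) and a summed level 9.70-fold lower (9.33 to 10.1). Slco1a1, an organic anion transporter gene (chromosome 6, 141907282 to 141946962), had 0 counts in ob against 87 and was at least 101-fold lower. Cyp7b1, an oxysterol hydroxylase gene (chromosome 3, 18071950 to 18243338), was 33.6-fold lower (18.1 to 69.4), and Elovl3, a fatty acid elongase gene, 31.4-fold lower (14.4 to 81.3). Mup7 lies on chromosome 4 from 60066469 to 60070475, in a family of near-identical genes that includes Mup15, 19.4-fold lower (17.2 to 21.9), and its reads may belong to other members. Serpina1e, an antitrypsin gene with close copies, was 24.1-fold lower (20.9 to 28.1), and Igfbp2, an insulin-like growth factor binding protein gene, 40.1-fold lower (19.5 to 95.7). Cytosolic ribosomal protein genes were lower in 55 of 74 members and higher in 0 (median -1.38, percentile 0.0, at most -0.30 under any scaling), with Rplp0 3.37-fold lower (2.28 to 4.97). Nuclear-encoded subunits of respiratory complexes II to V were lower in 12 of 35 and higher in 0 under TMM scaling (median -0.63, percentile 0.435), but their median was 0.44 under plain library totals. Complex I subunits were higher in 3 of 17 and lower in 3 (median -0.49, percentile 2.54, but 0.54 under plain library totals). Secreted hepatocyte proteins were lower in 9 of 27 and higher in 1 (median -0.51, percentile 5.83, but 0.62 under plain library totals), with Apoa1, the main apolipoprotein gene of high-density lipoprotein, 3.77-fold lower (3.48 to 4.08).

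Markers of other liver cells and of stress had list medians from -0.82 to 0.48 in ob. Of 13 fibrosis markers 3 were higher and 1 lower (median 0.44, 0.20 with counts of 0 at the floor, percentile 85.6), with Col1a1 3.48-fold higher (1.62 to 8.92) and the proteoglycan gene Dcn 2.31-fold lower (1.5 to 3.52). Of 12 endothelial markers 5 were higher and 0 lower (median 0.48, 0.06 with counts of 0 at the floor, percentile 68.1), with Stab1, a scavenger receptor gene of liver sinusoids, 4.30-fold higher (1.90 to 12.0). Macrophage markers were higher in 3 of 18 and lower in 3 (median -0.31, percentile 16.3, but up to 0.79 under other scalings). Acute phase genes were higher in 5 of 16 and lower in 1 (median 0.27, 0.16 with counts of 0 at the floor, percentile 80.8), with Orm2, an orosomucoid gene, 3.30-fold higher (1.44 to 9.29), and integrated stress genes higher in 4 of 10 and lower in 1 (median 0.09, percentile 58.8). Oxidative stress genes were higher in 2 of 15 and lower in 5 (median -0.82, percentile 3.71, but 0.30 under plain library totals), with Gclc, the gene of the first step of glutathione synthesis, 4.41-fold higher (2.17 to 10.4) and the lipid peroxidase gene Gpx4 3.13-fold lower (2.12 to 4.62).

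In total 1846 of 5347 features were at least 2-fold higher and 830 lower in ob, of which 798 and 635 also had a counting interval that excluded equality. The split was 3295 to 249 under plain library totals, 2243 to 576 under the submitters' scaling and 2427 to 495 with the features resembling mtDNA genes left out of the total. Libraries simulated with no difference except counting noise gave 628 higher and 144 lower calls on average, and 586 of the higher features had 0 counts in wild-type.

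The comparison of NASH with wild-type asked how the RNA of liver mitochondria differs in steatohepatitis. Markers of macrophages and of fibrosis were higher in the NASH library. Gpnmb, a glycoprotein gene of lipid-laden macrophages, had 125 counts against 0 and was at least 36.9-fold higher, Mmp12, the macrophage elastase gene, was at least 31.3-fold higher, and Col1a1, the main fibrillar collagen gene, was 9.86-fold higher (4.56 to 25.3). Messenger RNAs of many hepatocyte products were lower, with Mup7 206-fold lower (125 to 368), Scd1 35.7-fold lower (20.7 to 67.7) and the fibrinogen gene Fga 22.4-fold lower (18 to 28.3).

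Of 18 macrophage and leukocyte markers 14 were higher and 0 lower, with a median of 1.55 (percentile 100) and a summed level 3.58-fold higher (3.11 to 4.14). Gpnmb lies on chromosome 6 from 49036518 to 49058182, and Mmp12 on chromosome 9 from 7344381 to 7369499. The lysozyme gene Lyz2 was 5.67-fold higher (3.60 to 9.34) and Cd5l, a gene of liver macrophages, 3.98-fold (2.49 to 6.64). Outside the list, but among the largest increases, were Clec7a, a fungal pattern receptor gene, at 9.55-fold (3.85 to 30.6), Ctss, a lysosomal protease gene of antigen-presenting cells, at 6.63-fold (3.62 to 13.3), and Mpeg1, a macrophage perforin gene, at 4.42-fold (2.89 to 7.02). Of 13 fibrosis and stellate cell markers 9 were higher and 2 lower, with a median of 1.74 (1.25 with counts of 0 at the floor, percentile 100) and a summed level 2.76-fold higher (2.3 to 3.34). Col1a1 lies on chromosome 11 from 94936224 to 94953042, and Col3a1, another fibrillar collagen gene, was 3.37-fold higher (2.17 to 5.41). Of 12 endothelial markers 4 were higher and 1 lower (median 0.37, 0.00 with counts of 0 at the floor, percentile 89.3), and their summed ratio was 0.988 (0.687 to 1.42). Of 11 lipid droplet genes 4 were higher and 2 lower (median 0.00, percentile 71.4), with the lipoprotein lipase gene Lpl 17.9-fold higher (6.73 to 67.3), Cd36 5.60-fold (3.03 to 11.3) and Apoa4 5.42-fold (2.54 to 13.2). Cytosolic ribosomal protein genes were higher in 9 of 74 and lower in 0 (median 0.57, percentile 100), with Rpl4 2.36-fold higher (1.45 to 3.94). Gm10800, a predicted gene with repeats, was 60.6-fold higher (16.5 to 505) and is uncertain for that reason.

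All 27 secreted hepatocyte proteins were lower in NASH, with a median of -3.23 (percentile 0.05) and a summed level 7.65-fold lower (7.45 to 7.86). All 12 bile acid genes were lower (median -3.22, percentile 0.04, summed level 11.4-fold lower, 9.27 to 14.1), with the bile acid uptake carrier gene Slc10a1 17.6-fold lower (7.24 to 55.8) and the export pump gene Abcb11 14.2-fold (5.79 to 45.4). Of 23 xenobiotic genes 14 were lower and 1 higher (median -2.18, -1.98 with counts of 0 at the floor, percentile 3.43), with Cyp2d9 40.0-fold lower (16.8 to 125), Cyp2f2 31.1-fold (19.2 to 53.8) and the glucuronosyltransferase gene Ugt2b1 22.1-fold (13.2 to 40.0), each with close relatives. Sex- and growth-hormone-dependent genes were lower in 16 of 20 and higher in 0 (median -4.21, percentile 0.0), with a summed level 25.8-fold lower (23.4 to 28.5). Cyp7b1 was 119.8-fold lower (21 to 4777, with 1 count in NASH), Slco1a1 49.2-fold lower (13.2 to 412) and Elovl3 at least 23.7-fold lower.

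Genes of fatty acid and triglyceride synthesis were lower in 9 of 16 and higher in 1 (median -1.36, -0.69 with counts of 0 at the floor, percentile 6.00, but up to -0.09 under other scalings), with the elongase gene Elovl5 13.4-fold lower (6.54 to 32.0). Glucose-handling genes were lower in 7 of 13 and higher in 1 (median -1.61, 0.00 with counts of 0 at the floor, percentile 9.54, but up to -0.38 under other scalings), with the glucose transporter gene Slc2a2 8.16-fold lower (4.05 to 18.7). Acute phase genes were lower in 11 of 16 and higher in 2 (median -1.58, -1.69 with counts of 0 at the floor, percentile 2.56, but up to -0.31 under other scalings), with Crp, the C-reactive protein gene, 13.3-fold lower (7.00 to 28.5). Cholesterol genes were lower in 8 of 16 and higher in 1 (median -1.18, -0.98 with counts of 0 at the floor, percentile 5.96, but 0.10 with the features resembling mtDNA genes left out of the total). Stress and oxidant-defence genes moved both ways. Of 10 integrated stress genes 4 were higher and 4 lower (median 0.46, 0.34 with counts of 0 at the floor, percentile 94.1), with the chaperone gene Hspa5 5.08-fold lower (3.71 to 7.07). Of 15 oxidative stress genes 5 were higher and 3 lower (median 0.01, percentile 87.9), with the peroxiredoxin gene Prdx1 3.92-fold higher (2.48 to 6.46).

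Oxidative metabolism had no common direction in NASH. Fatty acid oxidation genes were higher in 3 of 25 and lower in 6 (median -0.16, percentile 51, but up to 0.93 under other scalings), amino acid and urea genes lower in 2 of 11 (median -0.31, percentile 63.7, but up to 1.03), complex I subunits higher in 1 of 17 and lower in 4 (median -0.52, percentile 15.9, but up to 0.68) and complex II to V subunits higher in 4 of 35 and lower in 4 (median -0.14, percentile 74.9, but up to 1.13). Erythroid genes were lower in 5 of 5 (median -2.21, -2.35 with counts of 0 at the floor, percentile 1.42). Small nuclear RNAs had a median of -0.12, small nucleolar RNAs of 0.00 and long non-coding RNAs of 0.00, with 7 of 35 higher and 9 lower. Summed over all features, the ratios to wild-type were 0.911 (0.548 to 1.52), 2.33 (1.61 to 3.43) and 0.736 (0.638 to 0.849) for these 3 classes. The nuclear-retained RNAs had 1 higher and 1 lower of 6 (median -0.22, percentile 70.8, but up to 0.84 under other scalings), and Neat1 had 5 counts. All 5 microRNA-annotated features were lower (median -2.76), with the repeat copy AC087541.1 6.64-fold lower (6.50 to 6.79).

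In total 1088 features were at least 2-fold higher and 1700 lower in NASH, of which 249 and 760 also had a counting interval that excluded equality. The split turned over to 2496 to 818 with the features resembling mtDNA genes left out of the total and was 1458 to 1381 under plain library totals, and the lower count was 1041 with the ob library left out of filter and scaling. Libraries simulated with no difference except counting noise gave 571 higher and 566 lower calls on average, and 394 of the higher features had 0 counts in wild-type.

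The comparison of db with wild-type asked how the RNA of liver mitochondria differs with a mutated leptin receptor. Acute phase genes were higher in the db library, with Saa2, a serum amyloid A gene, at 370 counts against 0 and at least 50.4-fold higher. Genes of fatty acid oxidation, cholesterol synthesis and fat storage were higher as well, among them Cyp4a14 at 38.4-fold (29.0 to 52.0) and Apoa4 at 73.0-fold (37.0 to 169). Mup7 was 10.2-fold lower (9.33 to 11.1) and Cyp7b1 9.61-fold lower (6.25 to 15.3).

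Acute phase genes were higher in 13 of 16 and lower in 0, with a median of 2.22 (2.14 with counts of 0 at the floor, percentile 100) and a summed level 5.98-fold higher (5.58 to 6.42). The haptoglobin gene Hp held 66.5% of the list's db counts, and without it the level was 4.29-fold higher (3.87 to 4.77). Saa2 lies on chromosome 7 from 46751833 to 46754314, and its near-identical neighbour Saa1 was 65.4-fold higher (29.9 to 179). Apcs, the serum amyloid P gene, was 28.2-fold higher (4.89 to 1129, from 1 count), and Orm2 9.12-fold (4.08 to 25.3). Secreted hepatocyte proteins were higher in 14 of 27 and lower in 0 (median 1.02, percentile 77.9), with the complement gene C3 7.18-fold higher (6.76 to 7.63) and the retinol-binding protein gene Rbp4 5.28-fold (4.64 to 6.04).

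Cholesterol genes were higher in 12 of 16 and lower in 0, with a median of 1.76 (1.64 with counts of 0 at the floor, percentile 100). Fatty acid oxidation genes were higher in 13 of 25 and lower in 1, with a median of 1.13 (0.81 with counts of 0 at the floor, percentile 99.8) and a summed level 12.3-fold higher (10.8 to 14.2), but 4.98-fold (4.26 to 5.84) without Cyp4a14 (chromosome 4, 115486200 to 115496142). Its copy Cyp4a10 was 12.8-fold higher (9.58 to 17.5). Vnn1 was 18-fold higher (4.83 to 151). Fatty acid and triglyceride synthesis genes were higher in 11 of 16 and lower in 1 (median 1.24, percentile 99.0), with Srebf1 14-fold higher (5.34 to 52.1), the triglyceride synthase gene Dgat2 4.51-fold (3.04 to 6.96) and Scd1 2.51-fold (2.26 to 2.80). Lipid droplet genes were higher in 6 of 11 and lower in 2 (median 1.84, 0.93 with counts of 0 at the floor, percentile 99.5), with Cd36 10.3-fold higher (5.80 to 20.1) and G0s2 at least 7.76-fold higher.

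Glucose-handling genes were higher in 8 of 13 and lower in 3 (median 1.47, 0.71 with counts of 0 at the floor, percentile 94.6), with Pck1 9.86-fold higher (4.68 to 24.9), the insulin receptor gene Insr 6.22-fold (3.18 to 13.9) and the glucose-6-phosphate carrier gene Slc37a4 6.13-fold (3.90 to 10.2). Bile acid genes were higher in 9 of 12 and lower in 2 (median 1.65, percentile 99.5), with Abcb4, the phospholipid export gene, 5.03-fold higher (3.58 to 7.27) and the 12-alpha-hydroxylase gene Cyp8b1 4.78-fold (3.69 to 6.28). Amino acid and urea genes were higher in 5 of 11 and lower in 0 (median 0.84, percentile 91.1), with Cps1 7.85-fold higher (6.03 to 10.4). Xenobiotic genes were higher in 13 of 23 and lower in 2 (median 1.27, 1.10 with counts of 0 at the floor, percentile 97.6), with Por, the reductase gene that serves cytochromes P450, 19.3-fold higher (11.8 to 34.0) and Cyp2a5 15.3-fold (10.6 to 23.0). On this list 16 members made at the endoplasmic reticulum had a median of 1.83 and 6 cytosolic ones of -0.36. Whether this split comes from the preparation was not tested. Among the largest increases outside the lists were Abhd15, at 37.2-fold (6.51 to 1484), Slc47a1, a drug export carrier gene, at 33.1-fold (5.77 to 1323), and Lrp4 at 29.8-fold (5.19 to 1194), each from 1 count in wild-type.

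Sex- and growth-hormone-dependent genes were lower in 11 of 20 and higher in 6 (median -1.09, percentile 0.02), with Mup15 8.92-fold lower (8.05 to 9.89) and Elovl3 6.17-fold lower (3.83 to 10.2), while the male-typical hydroxylase gene Cyp4a12a was 7.49-fold higher (5.33 to 10.9). Cytosolic ribosomal protein genes were lower in 28 of 74 and higher in 0 (median -0.68, percentile 0.0, at most -0.09 under any scaling). Macrophage markers were lower in 7 of 18 and higher in 3 (median -0.60, percentile 2.73), with Cd74, a gene of antigen presentation, 2.01-fold lower (1.35 to 2.97) and Clec4f, a Kupffer cell receptor gene, 2.69-fold higher (1.77 to 4.23). Fibrosis markers were higher in 4 of 13 and lower in 0 (median 0.26, 0.00 with counts of 0 at the floor, percentile 50.8). Endothelial markers were higher in 8 of 12 and lower in 0 (median 1.26, 0.82 with counts of 0 at the floor, percentile 98.3), with Stab1 4.08-fold higher (1.77 to 11.6). Erythroid genes were lower in 4 of 5 (median -1.90, percentile 0.02).

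Complex I subunits were higher in 5 of 17 and lower in 3 (median 0.64, percentile 96.0, but -0.02 with no filter). Their summed level was 310 CPM in db and 318 in wild-type. Complex II to V subunits were higher in 7 of 35 and lower in 3 (median 0.15, percentile 76.9), with Cox6a1 of cytochrome c oxidase 3.77-fold higher (1.89 to 8.53). Oxidative stress genes were higher in 1 of 15 and lower in 1 (median -0.54, percentile 7.51, but 0.06 under plain library totals). Integrated stress genes were higher in 2 of 10 (median 0.73, percentile 90.3, but -0.04 with no filter). Neat1 was 6.36-fold higher (2.98 to 16.2) and Malat1 1.42-fold (1.09 to 1.86), while small nuclear RNAs had a median of -0.77 (-1.29 with counts of 0 at the floor), small nucleolar RNAs of 0.08 and long non-coding RNAs of 0.00, with 9 of 35 higher and 2 lower. Summed over all features, the ratios to wild-type were 0.681 (0.434 to 1.08), 1.07 (0.737 to 1.57) and 1.67 (1.5 to 1.86) for these 3 classes. Of the 5 microRNA-annotated features 4 were lower (median -1.23). In total 1541 features were at least 2-fold higher and 1147 lower, of which 793 and 570 also had a counting interval that excluded equality. The split was 2049 to 764 under median-of-ratios scaling, 2097 to 631 under plain library totals and 2103 to 729 under the submitters' scaling, but it turned over to 2874 to 3934 with no filter, and was 985 to 705 with the ob library left out of filter and scaling. Libraries simulated with no difference except counting noise gave 601 higher and 295 lower calls on average. In db, 415 of the higher features had 0 counts in wild-type, and its strain background differs from that of wild-type by its genotype label.

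**Figure D2:**
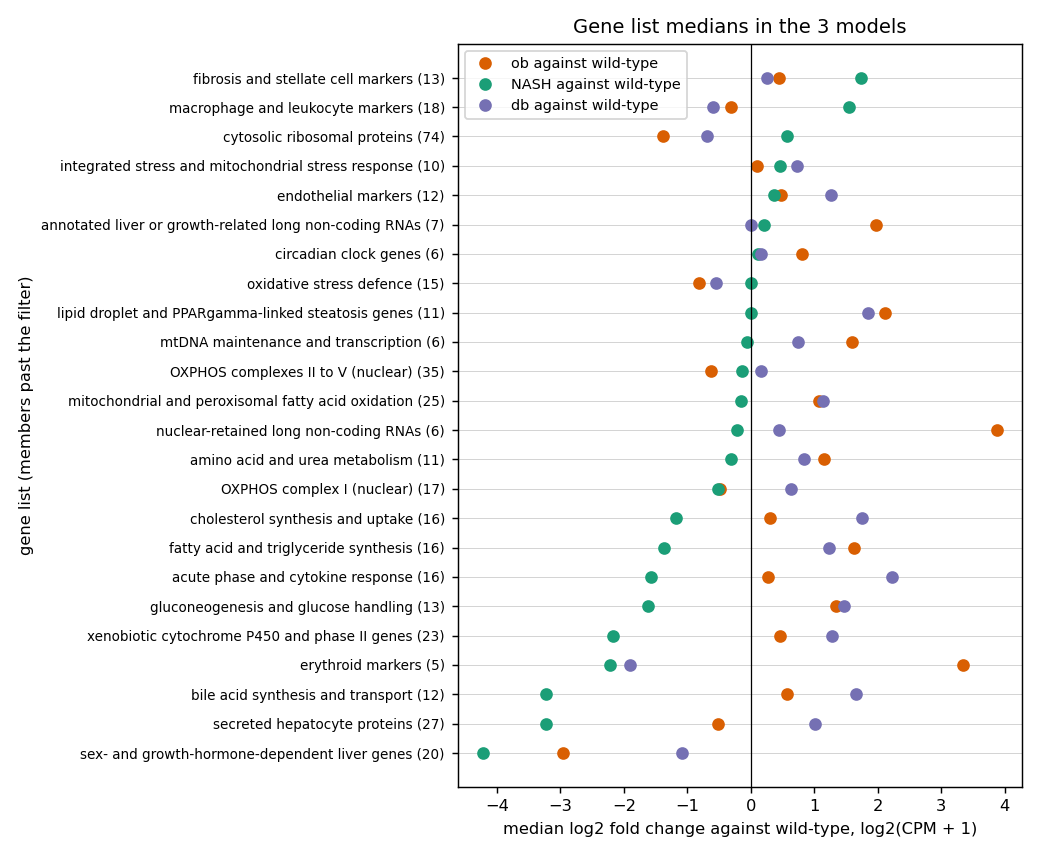
Median log2 fold change against wild-type (horizontal axis) of the 24 gene lists with at least 5 measured members (vertical axis), 1 point for each of the 3 models under TMM scaling. Secreted hepatocyte proteins lie at -3.23 in NASH and 1.02 in db and nuclear-retained RNAs at 3.87 in ob, while medians near 0, such as secreted proteins in ob (-0.51) and complex II to V subunits in ob (-0.63), turn above 0 under plain library totals.

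The comparison of db with ob set the receptor mutant against the hormone mutant. Saa2 was 58.6-fold higher in db (30.5 to 129) and Saa1 42.8-fold (30.1 to 62.9), while Neat1 was 48.0-fold lower (39.7 to 58.5), Malat1 18.3-fold lower (16.2 to 20.8) and the hemoglobin gene Hbb-b1 58.2-fold lower (31.5 to 122). Acute phase genes were higher in db in 13 of 16 and lower in 0 (median 2.03, 2.15 with counts of 0 at the floor, percentile 100), with Hp 5.98-fold higher (5.69 to 6.29). Cholesterol genes were higher in 11 of 16 and lower in 0 (median 1.45, percentile 99.98). Secreted hepatocyte proteins were higher in 23 of 27 and lower in 0 (median 1.5, percentile 99.97).

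Sex- and growth-hormone-dependent genes were higher in db than in ob in 15 of 20 and lower in 1 (median 1.51, percentile 100), with Slco1a1 at least 24.7-fold higher and Cyp4a12a 9.43-fold higher (7.61 to 11.8). Ugt1a8 was 25.7-fold higher (12.1 to 65.1) and Ugt1a7c 20.1-fold (10.3 to 45), which are glucuronosyltransferase genes with shared exons, so their reads cannot be assigned with certainty. Complex II to V subunits were higher in 14 of 35 and lower in 0 (median 0.89, percentile 99.99), with Cox6a1 4.93-fold higher (3.10 to 8.12). Fatty acid and triglyceride synthesis genes were lower in 6 of 16 and higher in 3 (median -0.61, percentile 0.35), with Mlxipl 40.8-fold lower (18.6 to 112), Scd1 3.58-fold (3.43 to 3.74) and the citrate lyase gene Acly 2.88-fold (1.91 to 4.48). Plin4 was 47.0-fold lower (8.15 to 1884), and Gclc 6.64-fold lower (3.74 to 12.8). Summed over all features, small nuclear RNAs were 9.66-fold lower in db (7.34 to 12.9), small nucleolar RNAs 10.8-fold (8.86 to 13.2) and long non-coding RNAs 6.45-fold (6.14 to 6.78). Past the filter, which most of these features met in ob alone, all 26 small nuclear (copies of U1, U2, U4 and U5 that can share reads) and all 26 small nucleolar RNA features were lower (medians -2.49 and -3.06, -3.30 and -3.11 with counts of 0 at the floor), as were 24 of 35 long non-coding features (median -2.30, -1.71 with counts of 0 at the floor), 4 of 6 nuclear-retained RNAs (median -3.09, -2.44 with counts of 0 at the floor, percentile 0.0) and 5 of 5 erythroid genes (median -5.34, -5.57 with counts of 0 at the floor, percentile 0.0). Among the largest decreases were also Mid1, a ubiquitin ligase gene, at least 33.0-fold lower, and A230050P20Rik, 110.8-fold lower (19.6 to 4406, with 1 count in db). In total 1048 features were at least 2-fold higher and 1614 lower in db, against 425 and 2275 under plain library totals and 386 and 2252 with the features resembling mtDNA genes left out of the total, and the split turned over to 439 and 177 with a filter of 50 counts. Libraries simulated with no difference except counting noise gave 134 higher and 260 lower calls on average, and the strain background differs between these mice by their genotype labels.

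The 3 comparisons with wild-type shared part of their genes. At least 2-fold higher in all 3 models were 450 features, among them Apoa4, Cd36 and Slc25a10, a mitochondrial dicarboxylate carrier gene, which was 21.5-fold higher in ob (3.74 to 860.1), 7.96-fold in NASH (1.10 to 349) and 10.6-fold in db (1.74 to 435) from 1 count in wild-type. The others with the largest smallest change were Zfp488, Acsf2, Agxt2, Ikbkg, Lyst, Olfr613 and Ccnl2, each with 0 counts in wild-type and between 2 and 7 in NASH. At least 2-fold lower in all 3 models were 227 features, led by Mup7, Mup15, Mup12, Mup17, Mup1, Mup14, Mup8, Cyp7b1, Elovl3 and Serpina1e. Independent lists of the same sizes would share 108 higher and 56.6 lower features. Simulated libraries with no difference except counting noise, against a shared simulated wild-type library, shared 309 and 24.4 on average, at most 340 and 36. Of pairs, ob and db shared 937 higher features (532 for independent lists, 426 with no difference) and 484 lower ones (178 and 43.8). The pair of ob and NASH shared 752 higher (376 and 389) and 374 lower (264 and 62.8), and NASH and db 497 higher (314 and 362) and 440 lower (365 and 112). The single wild-type library cannot be split, so part of each excess may come from that shared control. The lower count fell to 122 under median-of-ratios scaling and to 64 with the features resembling mtDNA genes left out of the total, and the higher count to 67 with a pseudocount of 5.

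**Figure D3:**
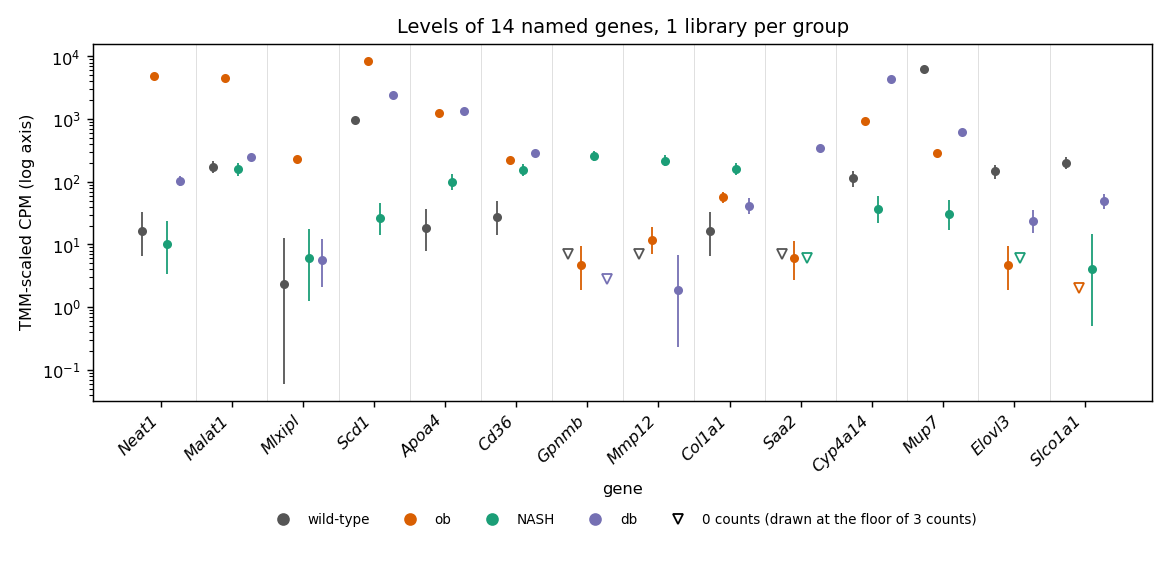
TMM-scaled CPM (log axis) of 14 named genes in the 4 libraries, with exact 95% Poisson intervals of single libraries and triangles for 0 counts drawn at the floor of 3 counts. Neat1 and Malat1 stand out in ob, Gpnmb and Mmp12 in NASH (125 and 106 counts against 0 in wild-type) and Saa2 in db, and Mup7 is lower in all 3 models than in wild-type.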

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

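All tests of depth and scaling below, and the test of cell types in NASH, were chosen after the results were seen, while the tests of gene span in ob and of endoplasmic reticulum messenger RNAs in NASH were chosen before the values they measure were seen. Each of the 11 gene lists below had a median log2 fold change against wild-type above 0 in 1 model and below 0 in another, by at least 0.5 each, and none of these differences was tested, since each model has a single library.

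Several hepatocyte lists stood high in db and low in NASH. Medians in db and NASH were 1.02 and -3.23 for secreted hepatocyte proteins, 1.65 and -3.22 for bile acid genes, and 1.27 and -2.18 for xenobiotic genes. They were 2.22 and -1.58 for acute phase genes, 1.47 and -1.61 for glucose-handling genes (0.00 in NASH with counts of 0 at the floor), and 1.76 and -1.18 for cholesterol genes, though the cholesterol median in NASH was 0.10 with the features resembling mtDNA genes left out of the total. Complex I subunits had 0.64 in db, but -0.02 with no filter, and -0.52 in NASH, but 0.68 with the features resembling mtDNA genes left out of the total. Macrophage markers went the other way, with 1.55 in NASH and -0.60 in db. Fatty acid and triglyceride synthesis genes had 1.62 in ob and -1.36 in NASH, erythroid genes 3.35 in ob and -2.21 in NASH, and cytosolic ribosomal protein genes 0.57 in NASH and -1.38 in ob. Under other scalings NASH medians reached -0.31 for acute phase, -0.38 for glucose-handling and -0.09 for fatty acid and triglyceride synthesis genes.

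In NASH, several lists of hepatocyte messenger RNAs were low while macrophage and fibrosis markers were high. Not all hepatocyte lists were low: medians were -0.31 for amino acid and urea genes, -0.16 for fatty acid oxidation and 0.63 for ketogenesis genes. Scaling as the whole cause was excluded, since the secreted protein median stayed at or below -1.88 over 6 scalings. A lower share of hepatocyte RNA that raises all other cell types alike was not borne out. The macrophage ratio exceeded the endothelial one (67 counts in NASH, 60 in wild-type) by at least 2.18 times at the nearest bounds. The fibrosis interval, however, overlapped the macrophage one. These bounds cover counting error of single libraries only, and a lower hepatocyte share with uneven ratios in other cells was not tested. A loss of messenger RNAs bound to the endoplasmic reticulum from the preparation remains open. Within the xenobiotic list, sorted by gene name, 16 members made there had a median of -2.69 and 6 cytosolic ones of -0.07, a difference of -2.62. At least 2-fold lower were 13 of the 16 and 0 of the 6. These sets do not cover all 23 members past the filter. A member that was also at least 2-fold lower fell in neither, since its name in the deposited table has another prefix. Which set it belongs to was not examined, so the 0 of the 6 may miss a lower cytosolic member. Col1a1, Gpnmb and Mmp12, also made at the endoplasmic reticulum, were higher. The same medians were 1.83 and -0.36 in db, the other way round, and 0.54 and 0.52 in ob. In db against ob they were 0.80 and -0.69. A difference between preparations in messenger RNA bound to the endoplasmic reticulum stays open for the lists high in db too. Lower expression of these genes in the livers of NASH mice, and more macrophages in them, stay open as untested biological explanations.

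In ob, Neat1, Malat1 and summed small nuclear and small nucleolar RNAs were high. Depth was excluded as the cause, since the lowest of their lower bounds was 4.64-fold, and so was scaling, since the log2 ratio of small nuclear RNA summed over all features had a lower bound of at least 2.21 over 6 scalings. More nuclear RNA in the ob preparation, unspliced RNA included, is a candidate explanation: the 1050 protein-coding genes of longest genomic span and the 1049 of shortest differed in median by -1.11 in db against ob (-1.23 to -0.97 over resampled genes), and against wild-type their medians were 0.67 and -0.06 in ob and 0.11 and 0.02 in db. Most features tested reached 10 counts in ob (4744, against 1368 in wild-type and 2895 in db), so the filter let in features high in ob. Nuclear RNAs did not rise alike: the nuclear-retained list without Neat1 and Malat1 was 1.56-fold higher in ob (1.23 to 2.01), and RNaseP_nuc was lower. Mapping or counting that differed for ob was not tested and stays open: of features with 10 to 29 counts 35.4% had whole-number counts in ob and 86.1% to 87.9% in the others. Higher transcription of these RNAs in ob livers stays open as an untested biological explanation.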

How the results depend on the processing

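No paired analysis was possible because each group has replicate 1 only, and no library of a group could be left out. Where counts of called features moved by over 1.5 times, or medians turned over under a setting, the values follow, and the cause was not tested except where the setting itself tests fewer or more features or moves the threshold. The depth limits all calls, since the floor of 3 counts lies between 1.99 CPM in ob and 6.95 CPM in wild-type. The submitters' scaling, the features resembling mtDNA genes left out, the interval criterion, counts of 0 at the floor and the libraries left out were added after the data were seen. Counts are given as higher and lower, against main counts of 1846 and 830 in ob, 1088 and 1700 in NASH, 1541 and 1147 in db, and 1048 and 1614 in db against ob.

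With a pseudocount of 0.1, with upper-quartile scaling and with counts of 0 at the floor, 8 of 8 counts stayed within 1.5 times of the main ones, and with the NASH library left out of filter and scaling 6 of 6 did. With the ob library left out, the NASH lower count was 1041 and the db counts 985 and 705. Calls whose counting interval also excluded equality numbered 798 higher in ob, 249 and 760 in NASH and 793 and 570 in db. At 1.5-fold, the ob lower count was 1282 and the db against ob higher count 1638. At 4-fold, counts were 909 and 264 in ob, 398 and 827 in NASH, 621 and 300 in db, and 144 and 701 in db against ob. With no filter, which tests more features, they were 4235 and 3441, 3612 and 4254, 2874 and 3934, and 2052 and 3768 in the same order. With a filter of 50 counts, which tests fewer, they were 319 and 120, 94 and 590, 493 and 93, and 439 and 177. With a pseudocount of 5, the NASH higher count was 574, the db counts 1018 and 684, the db against ob lower count 1024, and the number higher in all 3 models 67 in place of 450.

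Under plain library totals, counts were 3295 and 249 in ob, 631 lower in db and 425 higher in db against ob. Under median-of-ratios scaling, 764 were lower in db and 122 in all 3 models in place of 227, and under the submitters' scaling 729 were lower in db. With the features resembling mtDNA genes left out of the total, 495 were lower in ob, 2496 higher and 818 lower in NASH, 386 higher in db against ob, and 64 lower in all 3 models. The planned version of that setting, mtDNA-encoded genes left out, changes nothing, since the table holds 0 of them.

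The share of features resembling mtDNA genes was 38.1% in wild-type, 20.9% in ob, 52.1% in NASH and 18.7% in db without the feature resembling mt-Rnr2, and 71.9%, 45.3%, 87.2% and 39.6% without the 10 highest other features in the total. The order NASH, wild-type, ob, db held in both.

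List medians of at least 0.5 in size turned over as follows. Under plain library totals, complex II to V subunits in ob had 0.44, secreted proteins in ob 0.62, and oxidative stress genes 0.30 in ob and 0.0554 in db. With the features resembling mtDNA genes left out of the total, complex I subunits in NASH had 0.68, cholesterol genes in NASH 0.10, secreted proteins in ob 0.00875, and in db against ob oxidative stress genes -0.0123 and endothelial markers -0.0176. With no filter, complex I subunits in db had -0.0178 and integrated stress genes in db -0.0431, and with the filter of 50 counts glucose-handling genes in db against ob had 1.06. Smaller medians also changed sign over the 6 scalings. In ob, complex I subunits reached 0.54, mitochondrial ribosomal proteins 0.67 and macrophage markers 0.79. In NASH, nuclear-retained RNAs reached 0.84, mtDNA maintenance genes 0.85, fatty acid oxidation genes 0.93, amino acid and urea genes 1.03 and complex II to V subunits 1.13. In db against ob, complex I subunits fell to -0.05, fatty acid oxidation genes to -0.13, lipid droplet genes to -0.21, amino acid and urea genes to -0.41, ketogenesis genes to -0.44 and integrated stress genes to -0.45. Under median-of-ratios scaling 129 list and class medians moved by less than their sampling error over members and 11 by more, and under upper-quartile scaling 106 and 2. Under plain library totals 79 moved by less, 25 by more and 4 turned over. With the features resembling mtDNA genes left out of the total, these numbers were 79, 24 and 5.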

Other observations

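The test of the spread of the features resembling mtDNA genes was chosen after their values were seen, and the test of their ratios before it was computed. Several control genes differed between the libraries. Nnt, the mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J mice, had 1 count in wild-type, 32 in ob, 0 in NASH and 47 in db, a ratio to wild-type of 9.17 in ob (1.53 to 373) and 19.2 in db (3.28 to 774). Gene-level counts do not show which exons were read, and the db label names C57BL/6J as strain beside a BKS genotype. Y-linked genes were counted in all 4 libraries, with Ddx3y at 3 counts in wild-type, 27 in ob, 11 in NASH and 14 in db, Eif2s3y at 1, 26, 2 and 5, Uty at 2, 17, 2 and 2 and Kdm5d at 0, 13, 0 and 2. Xist, the RNA of the inactive X chromosome in females, had 1 count in wild-type and 0 in the others. The 4 measured sex-linked genes had median log2 fold changes of 1.86 in ob, 0.31 in NASH and 0.82 in db (1.33, 0.41 and 0.47 with counts of 0 at the floor), at percentiles of 86.1, 67.7 and 77.0 among random lists.

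Some lists of mitochondrial and regulatory genes were thinly counted. Of 77 mitochondrial ribosomal protein genes 4 passed the filter, with medians of -0.33 in ob (but up to 0.67 under other scalings), -1.34 in NASH and -0.89 in db (-1.63 and -1.05 with counts of 0 at the floor), and Mrpl18 had 1 count in wild-type, 23 in ob, 2 in NASH and 3 in db. Of 26 genes of mtDNA maintenance and transcription 6 passed, with medians of 1.60 in ob (0.04 with counts of 0 at the floor), -0.06 in NASH (but up to 0.85 under other scalings) and 0.74 in db (0.00 with counts of 0 at the floor). Lrpprc, which encodes a protein that stabilises mitochondrial messenger RNAs, had 3, 39, 7 and 11 counts in wild-type, ob, NASH and db. Ketogenesis genes (3 measured) had medians of 0.96, 0.63 and 0.53 in ob, NASH and db (1.10, 0.67 and 0.71 with counts of 0 at the floor), and clock genes (6 measured) of 0.81, 0.12 and 0.15 (0.22, -0.09 and -0.04 with counts of 0 at the floor). Liver-related long non-coding RNAs (7 measured) had medians of 1.97 in ob (0.52 with counts of 0 at the floor), 0.21 in NASH (0.00 with counts of 0 at the floor) and 0.00 in db, and Mir22hg, the host transcript of a microRNA, had 0, 35, 2 and 0 counts. Percentiles among random lists were 4.57, 7.75 and 10.6 in ob, NASH and db for mitochondrial ribosomal proteins, and between 32.0 and 78.1 for the other lists of this paragraph. Of nuclear-encoded RNAs reported in mitochondria 2 passed the filter: RNase_MRP had 37 counts in wild-type, 1653 in ob, 17 in NASH and 122 in db, and RNaseP_nuc 85, 133, 85 and 196. The cytoplasmic structural RNAs past the filter were 2 loci of signal recognition particle RNA, with 10.8%, 20.8%, 9.52% and 8.50% of counts. The 18 cell cycle genes summed to 41, 36, 53 and 31 counts, the 10 cholangiocyte genes to 10, 33, 24 and 12, of which Spp1, also on the fibrosis list, had 3, 20, 16 and 9, and the adipocyte and pancreas genes to 19, 3, 9 and 2.

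Between 26.3% and 75.5% of each library was counted at 9 nuclear features that resemble mtDNA genes, in a preparation of mitochondria whose table has no mtDNA-encoded features. A candidate explanation is that reads of mtDNA transcripts were counted at nuclear copies: the standard deviation of the 9 log2 fold changes, averaged over the 3 models, was 0.37 against a median of 1.41 in random sets of 9 features, at percentile 0.0. This spread cannot decide, since several of the 9 are neighbours on chromosome 2 or 4 and could move together under nuclear transcription too. The random sets were matched only on the fifth of expression. Gm20594 had the lowest identity of the 9, at 88.4%. Transcription of each nuclear copy of its own cannot be told apart from such counting by the ratio of Gm13340 to Gm11512, which both resemble mt-Co1. That ratio was 430 in wild-type, 402 in ob, 627 in NASH and 331 in db, a range of 1.89 times between the bounds set for the test. If the first explanation holds, the share of these features may follow the share of mtDNA transcripts, but reads were not examined here. The origin of the 57-base repeat copies was not tested.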
